A study of Mus musculus with 2 samples.

How the data were processed

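Gene expression was measured by RNA sequencing of polyadenylated RNA from the suprachiasmatic nucleus (SCN), the hypothalamic nucleus that holds the central circadian pacemaker of mammals. The tissue came from wild-type C57BL/6 mice at postnatal day 68. Per the labels' protocols, 16 mice were kept in constant darkness for 7 days and then split into 2 groups of 8, which were entrained to a normal (NT) or a short (ST) T-cycle, a light-dark schedule of set period. Wheel running was recorded in darkness after 4 weeks, and brains were taken after 5 days in darkness, at circadian time 4 h. The SCN was cut from slices of 250 µm under a binocular microscope. RNA was extracted with a kit for nuclear or cytoplasmic RNA, and 500 ng went into DNase treatment, poly-A selection, depletion of ribosomal RNA and Illumina library preparation. The periods of the T-cycles, the RNA fraction kept, and the number of mice whose tissue entered each library are not given in the sources used here. Each group was represented by 1 library.

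The submitters' processing notes name CASAVA 1.8.2, TopHat 1.2, DESeq and the mouse build mm9, with no role or order. The counter and the DESeq settings are not given in the sources used here. The deposited table lists 24229 genes. Its estimated counts, labelled RC by the authors per the file headers, are not whole (tolerance 1e-06) for 42.4% of genes in the ST library and 43.1% in the NT library, as when reads are divided between overlapping or near-identical features. Genes with a fractional count in either library are described below as sharing reads, and their values are less certain. The authors also deposited RPKM values, which divide counts by gene length and library total, and RPM values, which sum to 1000000 in each library. Their comparison gives a fold change, its log2 and a p-value with an adjusted p-value for ST over NT, per the file headers. The deposited log2 fold change and fold are written as 0 wherever a library rounds to 0 reads, which holds for 3387 genes. A further 3 columns of mean values were not used, because their names do not tie each of them to a single sample.

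Gene positions are those of the deposited table. Of its Ensembl identifiers, 23161 were found in the GENCODE vM1 annotation of NCBIM37, the assembly also called mm9, and 99.6% of these overlapped the annotated gene. Chromosome codes and strand codes of the table were translated by that comparison. Another 24 symbols had been turned into calendar dates and were restored through their Ensembl identifiers.

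The fractional counts were rounded to whole numbers. Libraries were scaled by median-of-ratios size factors, 0.89 for ST and 1.12 for NT. The log2 ratio of ST to NT was taken on normalised counts plus a pseudocount of 0.5, and folds are ratios of normalised counts without it. Genes with a mean normalised count of at least 50 were kept, 14343 in all. The 95% interval of each ratio is an exact Clopper-Pearson interval of the ST share of both counts, rescaled by the size factors. It covers counting error only, since reads without molecular identifiers are not independent molecules. The total count was 19476800 in the ST library and 24790727 in the NT library.

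With a single library per group there is no estimate of biological spread, so no p-value was computed and every difference compares these libraries, not the conditions. In place of a test, a size rule of 2-fold was set, with the subset of genes whose whole interval lay beyond 1.5-fold. Each gene list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured genes was said to stand apart below 2.5 or above 97.5. The 26 gene lists, the thresholds and the rule for named genes were set before the data were examined. The rule takes the 10 highest and 10 lowest genes with a symbol, ranked by the interval bound nearest to no difference. It adds all measured members of the clock, SCN peptide and DNA methylation lists, up to 4 members of every other list by size of the log2 ratio, the most abundant member of control lists, and up to 10 genes per direction by the authors' adjusted p. A few genes are not reported here by name; they stay in the counts of genes and in the medians of the lists they belong to. Another 7 lists were added after the genes called by the authors had been seen.

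The calculations were tested on simulated data with Poisson counts for 14339 genes at the depths of both libraries, of which 200 were changed. All genes changed 2.5-fold or 4.0-fold passed the 2-fold rule, against 0% of those changed 1.5-fold, and 0 unchanged genes passed. The intervals held the true ratio for 95.3% of genes. Of 200 random lists of 20 genes, 5.0% stood apart, and 100% of 100 lists raised by 0.2 on the log2 scale did.

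Alternatives were scaling by total counts, TMM factors, filters of 10 and 200, a pseudocount of 5, size rules of 1.5-fold and 3-fold, unmatched random lists, the mean in place of the median, and an adjusted p of 0.1 in the authors' table. Genes with whole counts only, and random lists matched on GC content and length (5 and 3 classes) as well as expression (5 classes), were added after the data had been seen. Sequence alignments used BLAST with an E-value limit of 1e-05. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 with edgeR 4.0.16 for TMM factors only, and BLAST 2.17.0.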

Results

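SCN tissue of mice held on a short T-cycle (ST) was compared with that of mice held on a normal T-cycle (NT), with 1 RNA sequencing library per group, both taken at circadian time 4 h after 5 days in darkness. The series concerns the reprogramming of circadian behaviour by light and the part of DNA methylation in it, so clock genes, SCN peptides and the DNA methylation machinery are described first among the gene lists. The ST library held 19476800 counts over 23147 genes with a read, and the NT library 24790727 over 23430. Mitochondrial genes took 6.41% of counts in ST and 6.84% in NT, and the 10 most abundant genes took 6.00% and 6.36%. There were no replicates, and the intervals given here are 95% counting intervals of the ratio.

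Few genes differed by 2-fold. Plin4, a coat protein of lipid droplets, was 2.48-fold higher in the ST library (interval 2.04 to 3.04, 303 counts in ST and 154 in NT). The receptor gene Gpr6 was 2.01-fold higher (1.51 to 2.70), but fell short of 2-fold with a pseudocount of 5 (log2 ratio 0.96) and was not measured with a filter of 200 (mean normalised count 106). Pomc, the precursor of melanocortins and beta-endorphin, was 5.31-fold lower in ST (4.46 to 6.38, 144 counts against 966). Fmod, a proteoglycan of connective tissue, was 3.37-fold lower (2.63 to 4.35), the axon guidance receptor Robo3 3.82-fold lower (2.5 to 6.01) and the interferon-induced gene Ifit1 3.72-fold lower (2.5 to 5.72). Among 14343 measured genes, 3 were at least 2-fold higher in ST and 33 at least 2-fold lower, and the whole interval lay beyond 1.5-fold for 3 and 30 of them. The 33 comprised 12 genes with ordinary symbols, 7 clone-named loci, 13 microRNA-named loci and the small nuclear RNA 7SK. Within 1.2-fold lay 90.5% of genes, and the correlation of log2 normalised counts across genes, which are not independent replicates, was 0.996. Restricting the count to genes that share no reads left 1 higher and 12 lower, a choice added after the data had been seen.

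Several other genes differed by less than 2-fold, with intervals clear of 1. Ndn, the imprinted gene of necdin, was 1.58-fold higher in ST (1.55 to 1.61, 23589 counts against 18832). Fbln5, an elastic fibre protein, was 1.65-fold higher (1.5 to 1.8), Cdkn1a, the cell-cycle inhibitor p21, 1.82-fold (1.46 to 2.26), and the transcription factor Zbtb16 1.72-fold (1.44 to 2.07). The sulfotransferase Sult1a1 was 1.85-fold higher (1.42 to 2.43) and the uncharacterised gene 1700048O20Rik 1.71-fold higher (1.44 to 2.04). Plin4, Sult1a1 and Ifit1 share reads with other features. Among the genes named below, so do Nr1d1, Dbp, Rora, Hlf, Clock, Avp, Prok2, Dnmt3a, Dnmt3b, Tdg, Rpl11, Camk4, Mbp, Slco1a4, Glul, Hba-a1 and Oxt. In mm9 coordinates, Plin4 (ENSMUSG00000002831) lies on chromosome 17 from 56240017 to 56249011, Pomc (ENSMUSG00000020660) on chromosome 12 from 3954951 to 3960642, and Ndn (ENSMUSG00000033585) on chromosome 7 from 69493163 to 69494814.

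**Figure D1:**
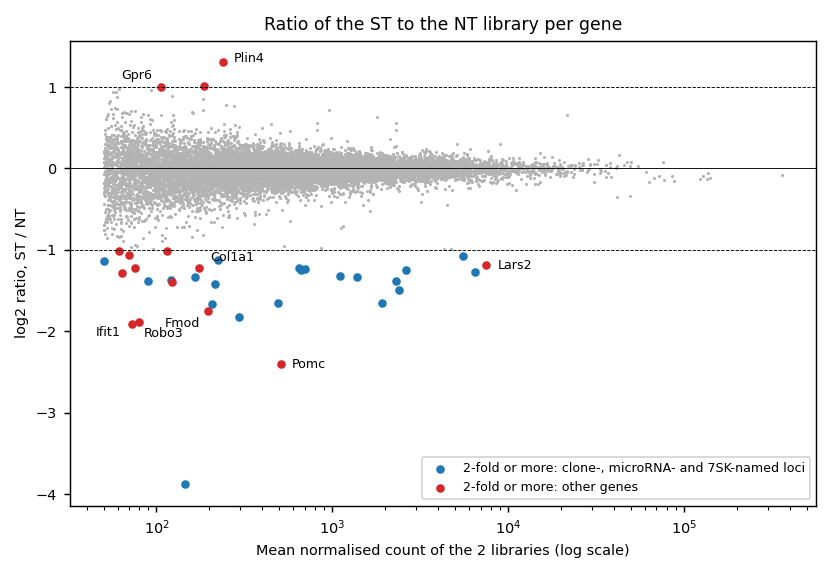
Log2 ratio of ST to NT (vertical axis) against the mean normalised count of the 2 libraries (horizontal axis, log scale), with 1 point per measured gene. Dashed lines mark 2-fold, red points are genes past it, and blue points are clone-named, microRNA-named and 7SK loci past it: 3 genes lie above the upper line and 33 genes or loci below the lower line.

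Core clock genes were close to equal in both libraries. Of 23 measured clock and clock output genes, 0 reached 2-fold, and the list median was -0.01 on the log2 scale, at percentile 30.6 of matched random lists. Per1, a light-responsive period gene, had a log2 ratio of 0.21 (fold interval 1.10 to 1.21), the repressor Nr1d1 0.16 (1.07 to 1.17) and the bZIP repressor Nfil3 0.36 (1.05 to 1.57). On the lower side were Fbxl21, an F-box protein acting on cryptochromes, at -0.23 (0.763 to 0.949), Dbp at -0.16 (0.852 to 0.944), Rora at -0.15 (0.867 to 0.943) and Hlf at -0.09 (0.900 to 0.981). The intervals of Per2 (0.948 to 1.04), Cry1 (0.916 to 1.08), Clock (0.983 to 1.10) and Arntl (0.948 to 1.15) all held 1. Together, 4 clock genes had an interval above 1 and 4 an interval below 1.

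SCN peptides went both ways. Vip, the peptide of ventral SCN neurons, had a log2 ratio of -0.24 (fold interval 0.819 to 0.880, 4988 counts in ST and 7419 in NT), and Nms, neuromedin S, -0.25 (0.738 to 0.958). Avp, vasopressin of the dorsal SCN, was at 0.21 (1.12 to 1.19), Sst at 0.24 (1.14 to 1.22), Gal at 0.48 (1.12 to 1.75), Cck at 0.54 (1.22 to 1.72) and the G-protein regulator Rgs16 at 0.16 (1.07 to 1.16). Grp (0.822 to 1.08), Prok2 (0.632 to 1.05) and the receptor Vipr2 (0.966 to 1.15) had intervals that held 1. The 19 measured genes had a median of -0.02, percentile 30.9, with 5 intervals above 1 and 4 below. The 11 transcription factors of SCN development and identity had a median of 0.01 at percentile 62.3, with Zfhx3 at 0.27 and Zic1 at 0.19.

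No clear difference was seen in the DNA methylation machinery at this depth. Dnmt1, the maintenance methyltransferase, had a log2 ratio of 0.04 (fold interval 0.970 to 1.10), and the de novo methyltransferase Dnmt3a 0.02 (0.961 to 1.07). The dioxygenase Tet2 was at 0.00 (0.923 to 1.08) and Tdg, which excises oxidised methylcytosine, at -0.13 (0.819 to 1.02). Only Mbd3 among the 14 measured genes had an interval clear of 1, at 0.10 (1.01 to 1.14). The list median was 0.01 at percentile 63.9, and 0 members reached 2-fold. Dnmt3b, Uhrf1 and Tet1 were below the count filter, with 31, 28 and 26 counts in the ST library.

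**Figure D2:**
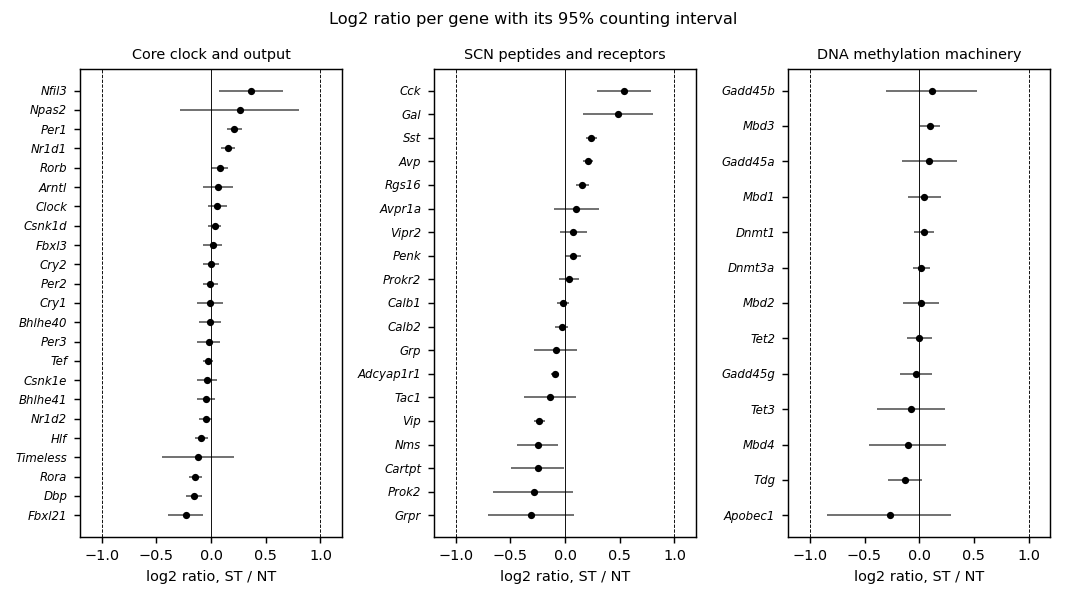
Log2 ratio of ST to NT (horizontal axis) for genes of the clock, SCN peptide and DNA methylation lists (23, 19 and 13 genes shown), as points with 95% counting intervals as lines. Dashed lines mark 2-fold, which 0 of these genes reached.

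Immediate early genes, which respond within minutes to neuronal activity and light, were higher in ST as a group. Of 20 measured members, 17 were higher and 13 had an interval above 1, with a median log2 ratio of 0.24 at percentile 100. Fos was at 0.63 (fold interval 1.45 to 1.66, 1953 counts against 1592), Egr4 at 0.67 (1.16 to 2.19), Fosb at 0.55 (1.22 to 1.76) and Junb at 0.54 (1.27 to 1.66). Heat shock and cold-inducible genes had a median of 0.10 at percentile 100, with 11 of 13 higher, led by Hspa1a at 0.72, Hspa1b at 0.68 and the co-chaperone Dnajb1 at 0.36. Hspa1a and Hspa1b are near-identical and share reads. Cytosolic ribosomal protein genes were higher by a small amount in 29 of 33 cases, 17 of them with an interval above 1, though 29 of the 33 share reads and the list could not be computed on whole counts. Their median was 0.12 at percentile 100, with quartiles of 0.06 and 0.15 and Rpl11 at 0.31.

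Neuronal signalling lists lay close to 0. The median was 0.01 for 28 glutamate signalling genes (percentile 62.0), -0.02 for 35 voltage-gated ion channels (12.4), -0.01 for 34 cAMP, calcium and MAPK genes (26.0), -0.03 for 34 axon guidance and adhesion genes (9.85) and -0.01 for 23 synaptic vesicle genes (37.5). Single members with larger ratios were the NMDA receptor subunit Grin2a at -0.62, the kinase Camk4 at -0.43 and the semaphorin Sema3c at -0.43. The 21 GABA signalling genes had a median of -0.04 at percentile 2.38, with Gabrb2 at -0.24 and Slc6a11 at -0.10, but the percentile was 11 against unmatched random lists and 20.4 by the mean. Nuclear genes of oxidative phosphorylation were at 0.03 (32 genes, percentile 95.5) and cholesterol synthesis genes at -0.04 (15 genes, percentile 5.20).

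Markers of oligodendrocytes, endothelium, microglia, meninges and blood were lower in ST. All 18 oligodendrocyte and myelin genes were lower, each with an interval below 1 and a median of -0.27 at percentile 0, among them Mbp at -0.33 (61994 counts in NT) and Aspa at -0.56. All 13 endothelial and mural markers were lower (median -0.32, percentile 0), including Slco1a4 at -0.42 and Pdgfrb at -0.41, and so were all 12 microglial markers (median -0.23, percentile 0), including P2ry12 at -0.51 and Cx3cr1 at -0.33. The collagen and matrix list, chosen to track meninges, had a median of -0.65 at percentile 0 with 13 of 13 lower, led by Col1a1 at -1.22, Igf2 at -0.98, Col3a1 at -0.94 and Col6a1 at -0.84, of which Igf2 and Col6a1 share reads. Astrocyte markers differed less, with a median of -0.08 at percentile 0.12. Of 12 astrocyte genes, 8 were lower, among them Aqp4 at -0.32, and 4 higher, among them Glul at 0.07, with 8 intervals below 1 and 2 above. The percentile of the astrocyte list was 2.90 against unmatched random lists and 3.28 by the mean. Blood genes, of which 4 of 5 share reads, were lower in 5 of 5 cases (median -0.23, percentile 0.31), with Hba-a1 at -0.23 and Ptprc at -0.58.

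Neighbouring regions gave a mixed picture. Of 10 measured neuropeptides of neighbouring hypothalamus, 5 were higher and 5 lower (median 0.04, percentile 82.2). The direction of that list turned with the setting, from 0.19 over 7 genes with a filter of 200 (percentile 99.9) to -0.13 over 16 genes with a filter of 10 (percentile 2.98). It was also lower with whole counts only (-0.12) and by the mean (-0.12). Pomc at -2.41 was the only member of that list past 2-fold, whereas Qrfp was at 0.59, Trh, the thyrotropin-releasing hormone, at 0.56, and Oxt, oxytocin, at 0.30. The list for thalamus, striatum, cortex and pituitary had a median of 0.06 at percentile 93.0 over 11 genes, with Prkcd at 0.23, 1 member at least 2-fold higher and 1, Pomc, at least 2-fold lower. Its mean was -0.10 at percentile 8.07. Ependymal, tanycyte and choroid plexus markers were at 0.06 (8 genes, percentile 93.8), with Dynlrb2 at 0.23, and stood apart as higher with a filter of 200 (7 genes, percentile 98.8). Of the 24 lists with a percentile, 7 were below 2.5 and 3 above the upper limit. If genes and lists varied independently, 1.2 lists would be due outside this range. Members of a list can move together and some lists share genes, so these numbers cannot be set against chance.

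**Figure D3:**
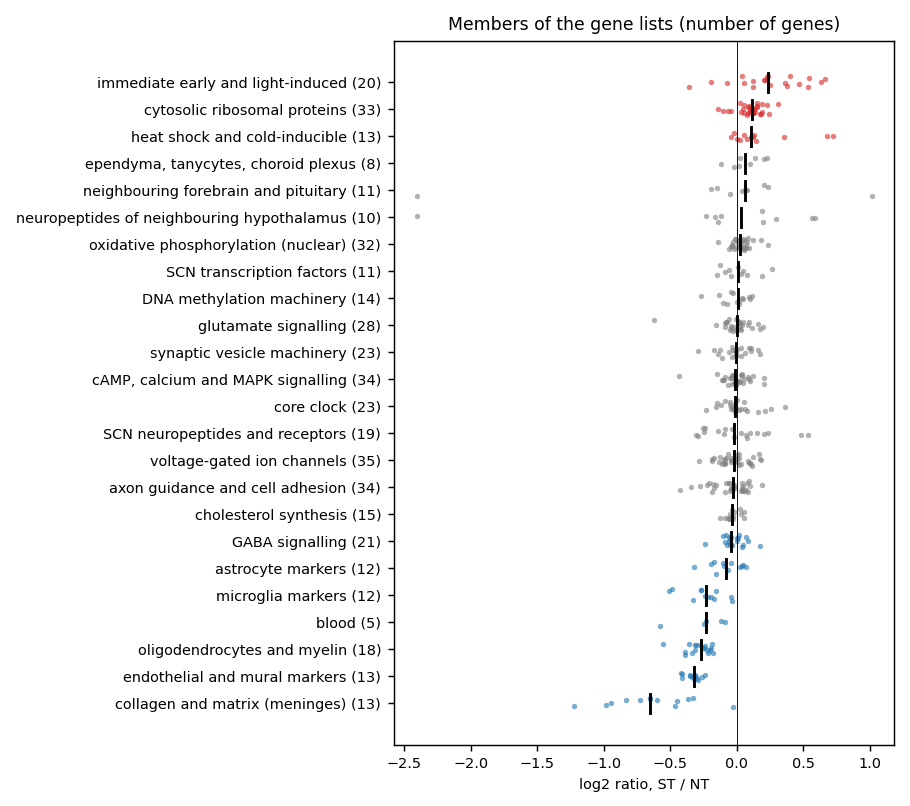
Log2 ratio of ST to NT (horizontal axis) for the measured members of 24 gene lists, with 1 point per gene and a black bar at each list median. Red lists lay above the upper limit of percentiles among matched random lists (3 lists, immediate early genes highest at 0.24), blue lists below the lower limit of 2.5 (7 lists, collagen and matrix lowest at -0.65), and grey lists between (14 lists).

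The authors' deposited table calls 10 genes higher and 39 genes or loci lower in ST at an adjusted p of 0.05. In the authors' deposited table the adjusted p was 2.09e-48 for Pomc, 2.72e-08 for Plin4, 0.000259 for Ndn, 0.000101 for Fbln5, 0.000468 for Fos and 0.00731 for Trh. The interneuron transcription factor Lhx6 is also called higher in the authors' deposited table, with 56 counts in ST and 21 in NT (3.37-fold, interval 2.01 to 5.85), as is the retinal gene Samd7 with 16 counts against 1 (20.2-fold, 3.14 to 847). Of the 39 lower calls in the authors' deposited table, 14 have ordinary gene symbols, 9 are clone-named loci, 13 are microRNA-named loci and 3 are structural RNAs, and 9 of the 39 share no reads. These calls rest on a single library per group, so they carry no biological replicate error.

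Short non-coding loci made up most of the strongest lower values. A 7SK locus (ENSMUSG00000065037, chromosome 9, 78023110 to 78023440) had 16 counts in ST and 305 in NT, 15.1-fold lower (9.15 to 26.8). Over all 86 loci named 7SK, of which 67 share reads, the summed counts were 114 and 530, 3.68-fold lower (3 to 4.55), and without that locus 98 and 225, 1.82-fold lower (1.43 to 2.33). The microRNA-named locus mmu-mir-2134-4 on chromosome 16 (11144248 to 11144304) was 3.13-fold lower (2.90 to 3.38, 827 counts against 3270), and its neighbour mmu-mir-689-2 was 2.82-fold lower (2.63 to 3.01). Further mmu-mir-2134-4 loci on chromosomes 9 and 13 and mmu-mir-2134-3 on chromosome 9 were 3.15-fold, 3.17-fold and 3.54-fold lower. All of these except mmu-mir-2134-3 share reads with other features, and polyadenylated libraries do not measure mature microRNAs.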

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

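No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. The number of genes at least 2-fold higher and lower in ST was 58 and 126 with a filter of 10 counts, 1 and 18 with a filter of 200, and 45 and 124 at 1.5-fold against 0 and 9 at 3-fold, by construction of those settings. In the simulated data, 26 unchanged genes lay at least 1.5-fold apart from counting error alone. With a pseudocount of 5 the number of genes at least 2-fold higher in ST was 1. Whole counts only, an alternative chosen after the data had been seen, gave 1 and 12, and left 9 of the authors' lower calls. The GABA list no longer stood apart with a filter of 10 counts (median -0.038), by its mean (-0.022) or against unmatched lists (-0.040), nor with the added settings of whole counts (-0.045) and lists matched on GC content and length (-0.040). The astrocyte list did not stand apart against unmatched lists (-0.080) or by its mean (-0.079). The oxidative phosphorylation list did stand apart by its mean (0.034), as did ependymal markers (0.10) and neighbouring hypothalamic peptides (0.19) with a filter of 200. The cause of these list changes was not tested. Fewer than 5 genes were left, so no value was given, for the ribosomal, blood and histone lists with whole counts, and for the blood, histone and arcuate lists with a filter of 200. The other 203 values of the lists set beforehand kept their call. Of those of the added lists, 49 kept it and 2 lost it, both of the arcuate and ventromedial list, with whole counts (-0.14) and by the mean (-0.18). Called list values reversed in 0 cases. Medians or means of lists set beforehand that did not stand apart changed sign in 16 cases, 12 of them to within 0.0149 of 0. The other 4 were the neighbouring hypothalamic peptides with a filter of 10 (-0.13), with whole counts (-0.12) and by the mean (-0.12), and the forebrain list by the mean (-0.10). Total-count scaling moved log2 ratios by 0.012 and TMM by 0.00013, and all 531 gene values under these scalings and the pseudocount of 5 stayed within the counting interval. Depth leaves an interval of 1.51 to 2.70 around the ratio of Gpr6 and of 1.55 to 1.61 around that of Ndn.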

Other observations

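The 7 gene lists used here were added after the authors' called genes had been seen, before the values of their members were known. The genes seen included Cdkn1a, which the authors' table calls only at an adjusted p of 0.1. The tests of an even loss of non-neuronal cells, of microglia or meninges as the whole source, of meningeal genes without those of the collagen list, and of the region around mir-2133-2 were chosen after the values they rest on had been seen.

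Mitochondrially encoded genes were slightly lower in ST. All 13 protein-coding genes had an interval below 1, with log2 ratios from -0.17 to -0.06 and a median of -0.12, while nuclear genes of oxidative phosphorylation had a median of 0.03. Of 29 measured interferon-stimulated genes, 29 were lower and 15 had an interval below 1, with a median of -0.28 at percentile 0, including Rtp4 at -1.01, Parp14 at -0.95, Gbp3 at -0.89 and the abundant B2m at -0.45. Among genes chosen after their values were seen, Cxcl10 had 4 counts in ST and 44 in NT (8.72-fold lower, interval 3.17 to 33.4), Ifit3 was 1.94-fold lower (1.70 to 2.22), and Lars2, a mitochondrial leucyl-tRNA synthetase, was 2.27-fold lower (2.19 to 2.36), all of which share reads. So do Gbp3, Meg3, Snhg11, Lhb, Tbx3 and Fkbp5 among the genes named in these observations. Both libraries held transcripts of Y-linked genes, with Ddx3y at -0.02 and Uty at -0.20, and Xist had 3 counts in ST and 2 in NT. Of 4 measured nuclear-retained RNAs, Meg3 was at 0.08 and Snhg11 at 0.02. Of the pituitary list only Lhb was measured, at 0.21.

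Genes of tissue next to the SCN differed between libraries, with Pomc and meningeal genes lower and Lhx6 higher in ST. The oligodendrocyte and myelin list, chosen to track the optic chiasm, was also lower, in 18 of 18 genes (median -0.27). Whether the ST tissue held less optic chiasm was not tested. More telencephalon or preoptic area in the ST tissue is argued against by 17 telencephalic genes (median -0.048), and an even loss of all non-neuronal cells by the gap of 0.569 between the astrocyte and collagen lists, above the 0.294 that their members' spread allows. Less meninges in the ST dissection may contribute: the 22 meningeal genes of the planned test had a median of -0.44 at percentile 0, past the -0.3 set beforehand. As 6 of them are also in the collagen list, the 16 others were taken alone, and had a median of -0.203 at percentile 0.16, with 13 lower and 8 intervals below 1, short of that bar. Whether less arcuate or ventromedial tissue underlies Pomc cannot be told apart from other sources, because 7 other genes of those nuclei had a median of -0.23, short of the -0.5 set beforehand for loss of that tissue but not clear of -0.25 by their spread, with Tbx3 at -0.85 but Fezf1 at 0.37. With whole counts only, 5 of them had a median of -0.14 at percentile 11.7, nearer to no loss, and the mean of the 7 was -0.18 at percentile 4.70, so the test rests on few genes. An effect of the T-cycle on these cells stays open and untested, as dissection and group coincide.

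Interferon-stimulated genes may be lower because the ST tissue held fewer microglia or less meninges, or because of a weaker interferon response. The microglial median of -0.23 lies within the interquartile range of the interferon list (-0.64 to -0.17). The oligodendrocyte (-0.27) and endothelial (-0.32) medians lie within it too, so this does not single out microglia. Whether microglia are the whole source cannot be told apart, since 13 of 32 measured interferon genes had a lower ratio than P2ry12, the lowest microglial marker, but only 2 lie wholly below its interval. These 2, Ifit1 and Ifit3, were among the genes that raised the question. For meninges, the interferon median minus the meningeal one was 0.159, above 0 as loss of that tissue would give, but -0.0742 without the collagen genes. Whether meninges are the whole source cannot be told apart, since 0 of the 32 lie wholly below Col1a1, though Ifit1 has a lower ratio. The lower values also extended to interferon genes not among the authors' calls, with the median of -0.28 given above. A response of the tissue to the T-cycle was not separable from its composition.

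Clone-named and microRNA-named loci, Lars2 and 7SK were lower in ST. A general fall in carry-over of RNA without poly-A tails is argued against by pooled structural RNAs other than 7SK (3607 counts in ST and 4708 in NT, ratio 0.967, interval 0.926 to 1.01). The 5 measured histone genes (median -0.036) also showed little difference, but 4 share reads and some carry such tails in non-dividing cells. Neither set covers 7SK or ribosomal RNA, so less carry-over of these alone stays open. Transcripts of the region around mir-2133-2 as the sole origin are argued against, since 9.09% of the called loci aligned to it (2 of 22, against 12 of 200 control loci). The locus mir-2133-2 is itself among the called loci, so its own alignment was fixed in advance. The region ended 6000 bases to each side of mir-2133-2, so a longer transcript reaching beyond it was not tested. Reads divided between similar loci are a candidate explanation for so many loci moving together, though not for the direction. Of the called loci, 86.4% (19 of 22) aligned to Lars2 or to another called locus, against 0 of 200 control loci, and 20 of 22 have fractional counts. Only 2 of the 22 aligned to Lars2 itself. Several called loci carry the same family name, such as mmu-mir-2134-4, so alignment between them was to be foreseen. Hits were kept by E-value alone, so near-identity was not measured. Control loci were searched only against the called loci, not against each other, so these shares are unlike. The called loci AC125254.2 and AC125254.3 overlap each other within Lars2, so their alignment follows from position. With Lars2 the called loci form 8 groups by alignment, the largest of 7 loci and the one that holds Lars2 of 3. A single repeated sequence behind all of them therefore cannot be told apart from several. Whether these loci or the region around mir-2133-2 hold ribosomal RNA sequence was not examined.

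A hypothesis raised by Plin4, Zbtb16 and Cdkn1a, genes known to respond to glucocorticoids, is that the ST mice had a stronger glucocorticoid response at sampling. It was tested on 28 other measured glucocorticoid-responsive genes, whose median of 0.08 lay at percentile 99.98 of matched random lists, with 21 higher and 8 intervals above 1. The upper quartile was 0.22, and genes beyond it include Sult1a1 at 0.89, Angptl4 at 0.60, Fkbp5 at 0.48 and Sgk1 at 0.34. Without the genes also in the clock or immediate early lists, 26 remained, at percentile 99.9. In this pair of libraries the result goes with the hypothesis but does not single it out. Immediate early genes (median 0.24) and heat shock genes (0.10) were also higher. Members of a list can move together, so the percentile cannot be set against chance. The size is small, hormone levels were not measured, and stress at sampling or a shift in the phase of the daily hormone rhythm stay open.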
